A study of Homo sapiens with 50 samples.

How the data were processed

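RNA was measured in MCF7 cells, a human luminal breast cancer line that expresses the estrogen receptor. The growth protocol calls them MCF7 scr without saying what scr means. Per the labels' protocols, the cells were serum-starved for 16 h in 0.1% fetal bovine serum (FBS), and then either harvested after starvation or given complete medium with 10% FBS for 4 h together with the vehicle DMSO, 3 nM RMC-4627, 35 nM RMC-4745 or 40 nM MLN0128. The series' design text describes RMC-4627 and RMC-4745 as selective inhibitors of mTORC1, the mTOR complex that phosphorylates the 4E-BP translation repressors and the S6 kinases. MLN0128 is an inhibitor of the mTOR kinase itself and therefore of both mTOR complexes. Doses were not matched in concentration, so values with the 3 compounds were compared at the single dose of each. From each culture, cytosolic RNA and RNA from the fractions of mRNAs with more than 3 ribosomes (polysome-associated RNA) were extracted in parallel, and libraries were made with Smart-seq2, which amplifies full-length cDNA and carries no molecular identifiers.

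The deposited values are whole-number counts of fragments per gene. Per the submitters' processing notes, reads were aligned with HISAT2 to GRCh37 and counted with featureCounts. Per the file headers, featureCounts version 1.6.2 counted fragments without regard to strand and left out fragments that mapped to several places or overlapped several genes. The HISAT2 version, the read trimming and the annotation release were not given in the sources used here. The unit was checked against each of the 50 files, which hold 63677 genes each and 0 lines without a gene identifier. Leaving out fragments of several places lowers the counts of genes with near-identical copies, such as ribosomal protein genes, which have many processed pseudogenes, and part of such a gene's fragments can be counted for a copy. Values of these genes, of the multi-copy RNA RN7SL1 and of the hair keratin gene KRT81, whose family members resemble each other, are therefore uncertain in level. Without strand, fragments of a gene and an antisense neighbour cannot be told apart.

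The labels name 4 biological replicates for each of 10 groups (5 conditions in 2 kinds of RNA) and split replicate 1 into technical replicates 1A and 1B, whose counts were summed, leaving 40 libraries. What the technical replication covered was not given in the sources used here. The labels do not say whether biological replicates were separate cultures grown on separate days, so the p-values measure the spread between these samples. Technical replicates differed by a coefficient of variation of 0.269 and biological replicates by 0.288 (edgeR common dispersion, square root), and 0 pairs of files held identical counts. Total counts per file ranged from 8301950 to 32553898 with a median of 23753071.5. Without molecular identifiers, amplified copies are not independent molecules, so depth bounds only the counting error.

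Gene identifiers were matched to GENCODE 29 for symbols and gene types: 52526 had a gene type and 52181 a current symbol. Coordinates are those of the deposited files in GRCh37, from the lowest start to the highest end of a gene's exons. Genes were filtered with edgeR's filterByExpr over the 10 groups (16976 genes kept), library sizes were scaled by trimmed mean of M values (TMM), and edgeR 4.0.16 in R 4.3.3 fitted a quasi-likelihood model with 1 mean per group over all 40 libraries and no further covariate. Cytosolic and polysome libraries of a culture were thus treated as independent, and their link enters only the alternatives with the culture as a block and with ratios. The common biological coefficient of variation was 0.284. Contrasts were each treatment against DMSO and each pair of inhibitors, in cytosolic RNA, in polysome RNA, and as the difference between both, an interaction term called the change in polysome association here. Polysome RNA was also contrasted with cytosolic RNA within DMSO. Genes with a Benjamini-Hochberg adjusted p under 0.05 over all tested genes in a contrast were called. A gene's level is given as edgeR's CPM, its counts relative to the TMM-scaled library size, as mean ± SD over n = 4 replicates. With 4 replicates against 4 the smallest exact two-sided permutation p is 0.0286.

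There were 28 gene lists, written from general knowledge before the data were examined, with 796 entries of which 795 were matched. They covered cytosolic ribosomal proteins, other mRNAs with a 5' terminal oligopyrimidine (TOP) tract, TOP non-coding hosts, eIF4E-sensitive mRNAs, nuclear-encoded respiratory chain subunits, mitochondrial ribosomal proteins, cholesterol synthesis, fatty acid synthesis, ATF4 targets, tRNA synthetases, FOXO targets, lysosome and autophagy, the serum response, E2F and S phase, G2 and mitosis, ribosome biogenesis, nucleotide synthesis, glycolysis and HIF1, estrogen receptor targets, proteasome, mRNAs with upstream open reading frames, polyamines, the mTOR pathway, interferon, mitochondrial-encoded mRNAs, untranslated nuclear RNA, luminal epithelial identity, and markers of other cell types. Each list was tested with camera in limma 3.58.1 against all other genes, with a preset inter-gene correlation of 0.01, and its adjusted p covers the 28 lists of a contrast. Camera was repeated with a correlation estimated from the residuals, which is stricter for lists whose members vary together. Adjusted p without further mention is from the preset correlation for lists and from edgeR's quasi-likelihood test for genes. Counts of called members are given over all tested genes and "adjusted over the list alone". List scores per culture (mean log2 CPM with a prior count of 2, or the polysome minus the cytosolic score) were compared with limma, a comparison added after the data were seen, and their 95% intervals come from it. Log2 ratios with 0.5 CPM added served only the naming of genes and the limma alternative on ratios.

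Genes were named by a rule fixed before the data were examined. It takes the 5 highest and 5 lowest log2 fold changes per treatment in cytosolic RNA and in polysome association among called genes with a mean of at least 10 CPM and all 4 values of one condition above all 4 of the other (3 and 3 for inhibitor pairs), up to 4 members of each described list with the smallest p, and 28 genes fixed by name. Pseudogenes and clone names were left out. ACTG2 with the inhibitors and RASD1 in starvation fell outside this rule and were chosen after their values were seen.

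Alternatives planned before the data were examined were an estimated inter-gene correlation, no filter on low counts, DESeq2 size factors in edgeR, library size only, the replicate number as a block, each culture left out in turn, a fit of only the groups compared, fry in place of camera, technical replicate 1A or 1B alone for replicate 1, the DESeq2 1.42.0 Wald test, limma on the polysome to cytosolic ratios, the variance of polysome RNA after regression on cytosolic RNA, the culture as a block, and a fold change of at least 1.5. Settings added after the data were seen were a fit without 4 doubted cultures, a fit without mitochondrial genes, list scores with the replicate number as a block, and contrasts of starvation with each inhibitor. The procedures were tested on simulated counts with 16577 genes. Changes were placed only among the more abundant genes, with the same mean in both kinds of RNA and no effect of the replicate number. Recovery in the data may therefore be lower, and false calls under a shared batch were not tested. For cytosolic RNA with MLN0128 against DMSO, edgeR recovered 14.9% of genes changed 1.5-fold, 61.2% of genes changed 2-fold and 98.5% of genes changed 4-fold, with 1 false call. For polysome association with RMC-4627, these shares were 2.99%, 13.4% and 83.3%, also with 1 false call, so edgeR mostly missed small changes in polysome association. On the same simulated counts DESeq2 recovered 23.9% of the 2-fold changes with 10 false calls and the regression on cytosolic RNA 43.3% with 3.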

Results

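Polysome profiling of MCF7 cells was used to ask how mTORC1-selective inhibitors, an inhibitor of the mTOR kinase, and the absence of serum changed mRNA levels and the loading of mRNAs on ribosomes. Cytosolic RNA and RNA bound to more than 3 ribosomes were sequenced in 5 conditions with n = 4 biological replicates each, so the 10 groups held 40 libraries after the technical replicates of replicate 1 were summed. Total counts per file lay between 8301950 and 32553898, and the lowest belonged to the polysome library of MLN0128 replicate 2. The next lowest file held 17638463 counts. On the first principal component (35.8% of the variance), which parted polysome from cytosolic libraries, 3 cytosolic libraries lay nearer the polysome side: DMSO replicate 1 at -20.5, RMC-4745 replicate 1 at -18.9 and starvation replicate 4 at -26.4, against -82.7 to -43.5 for the other cytosolic libraries. Of the polysome libraries, starved replicates 2, 3 and 4 lay nearest the cytosolic side, at -2.82, 13.6 and 27, against 36.6 to 88.5 for all other polysome libraries, and were kept. Without starved replicate 2, 3 or 4, polysome association in starvation changed for 186, 138 and 199 genes, against 200 with all, and no fit left out all 3 together. Counts of changed genes in cytosolic RNA and polysome association are therefore also given without the cultures of the 3 cytosolic libraries and the shallow MLN0128 replicate 2. Of 16 matched markers of fibroblasts, basal or mesenchymal cells and leukocytes, 3 were expressed above the count filter, and edgeR called 0 of these 3 in cytosolic RNA in any treatment.

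In cells given serum and DMSO, polysome RNA held a smaller share of the RNAs that cytosolic ribosomes do not translate than cytosolic RNA did. All 13 mRNAs encoded by mitochondrial DNA were lower in polysome than in cytosolic RNA, with a median log2 difference of -2.65 (13 lower adjusted over the list alone, camera adjusted p = 9.3e-29 and adjusted p = 0.00803 with an estimated correlation). Nuclear or untranslated RNAs followed, with 10 of 11 lower and a median of -2.89 (10 lower adjusted over the list alone, adjusted p = 6.11e-07, adjusted p = 0.00112 with an estimated correlation). Mitochondrial-encoded mRNAs were still abundant in polysome RNA, with a list score of 8.24 ± 0.39 log2 CPM. Nuclear-encoded respiratory chain mRNAs stood at 8.255 ± 0.23 there. Proteasome subunit mRNAs were enriched, with 21 of 31 higher and 1 lower (21 and 1 adjusted over the list alone, median 0.77, adjusted p = 7.95e-13, adjusted p = 0.0427 with an estimated correlation). Among cytosolic ribosomal protein mRNAs, 59 of 78 were higher and 4 lower (61 and 4 adjusted over the list alone, median 0.77, adjusted p = 3.87e-15), but adjusted p = 0.394 with an estimated correlation. edgeR called 6844 of 16976 genes (3343 higher, 3501 lower). Scaled by library size only, 2082 were higher and 5781 lower, and the median over all genes moved to -0.47 on the log2 scale, so both directions are relative to the average mRNA.

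Without serum, the cytosolic mRNAs of the serum response, of ribosome assembly and of cholesterol synthesis were lower than in cells given serum and DMSO, and FOXO target mRNAs were higher. The DMSO cells had been starved for 16 h as well and then got serum for 4 h, while the starved cells were harvested after starvation. Lower or higher in starvation is thus relative to cells given serum again, and cells never starved were not measured. ACTG2, a smooth muscle actin gene induced through serum response factor (chromosome 2: 74119441-74146992), stood at 242 ± 41.2 CPM with DMSO and at 2.76 ± 0.83 CPM in starved cells, a log2 change of -6.45 (95% interval -6.96 to -5.95; adjusted p = 2.69e-23). Among called genes of at least 10 CPM whose replicate values did not overlap, the next lowest changes were those of the keratin genes KRT81 (-5.01, SE 0.46) and KRT80 (-4.33, SE 0.30), of FHL2, a LIM domain cofactor (-4.99, SE 0.26), and of the cytokine gene IL24 (-4.09, SE 0.30). Within the same limit, the highest were those of TP53INP1, a p53-induced gene (2.51, SE 0.29), of SOCS2, a suppressor of cytokine signalling (2.43, SE 0.30), of HBP1, a transcriptional repressor that restrains the cell cycle (2.42, SE 0.23), of TXNIP, which restrains glucose uptake (2.29, SE 0.16), and of TRERF1 (2.16, SE 0.23). TXNIP (chromosome 1: 145438469-145442635) stood at 167 ± 18.8 CPM with DMSO and at 816 ± 165 CPM in starved cells.

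By gene list, 18 of 31 serum response mRNAs were lower and 0 higher in starved cells (19 lower and 1 higher adjusted over the list alone, median -1.47, adjusted p = 4.17e-19, adjusted p = 0.00186 with an estimated correlation). Among them were VCL, the focal adhesion gene of vinculin (-2.79, SE 0.25), the phosphatase gene DUSP4 (-2.49, SE 0.26) and the actin gene ACTG1 (-2.32, SE 0.22). EGR1, an immediate early transcription factor, was lower by a log2 change of -1.54 (adjusted p = 0.000585). Ribosome biogenesis factors were lower in 32 of 45 cases (37 adjusted over the list alone, median -1.08, adjusted p = 7.61e-32, adjusted p = 1.33e-05 with an estimated correlation). NOP16 was at -1.69 (SE 0.16), PNO1 at -1.45 (SE 0.16) and NOP56 at -1.36 (SE 0.15). Cholesterol synthesis genes were lower in 18 of 25 cases (19 adjusted over the list alone, median -0.92, adjusted p = 3.28e-15, adjusted p = 6.24e-06 with an estimated correlation). Examples were the sterol enzyme genes MSMO1 (-1.52, SE 0.20), SQLE (-1.27, SE 0.16) and DHCR24 (-1.26, SE 0.19). FOXO targets were higher in 9 of 22 cases (10 adjusted over the list alone, median 0.52, adjusted p = 8.89e-10, adjusted p = 0.00151 with an estimated correlation). Among these were KLHL24 (3.14, SE 0.32), the PI3K inhibitor gene PIK3IP1 (2.71, SE 0.28) and the cyclin gene CCNG2 (2.61, SE 0.32). The cell cycle inhibitor gene CDKN1B (1.14, SE 0.21) and the receptor gene ERBB3 (0.73, SE 0.16) were also higher. Of 36 E2F and S phase genes 10 were lower (12 adjusted over the list alone, median -0.47, adjusted p = 1.34e-05), but adjusted p = 0.159 with an estimated correlation. CDC6 (-1.001, SE 0.22) and ORC6 (-1.02, SE 0.23), which load replication origins, were among them.

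The eIF4E-sensitive list, mRNAs described as dependent on the cap-binding factor, had 6 of 20 members lower in starved cytosol (7 lower and 2 higher adjusted over the list alone, median -0.37, adjusted p = 0.00475, adjusted p = 0.0126 with an estimated correlation). MYC, a transcription factor of growth, was lower by -0.64 (adjusted p = 0.00509), and the sterol genes HMGCR (-0.93, adjusted p = 0.0202) and LDLR (-0.67, adjusted p = 0.0293) also passed, although each of these 3 calls was lost under at least 1 alternative setting. In all, edgeR called 2384 genes in starved cytosolic RNA, 897 higher and 1487 lower. Without the 4 doubted cultures, 1927 were called, 1736 of them shared.

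In polysome RNA, 75 of 78 cytosolic ribosomal protein mRNAs were lower in starved cells than with DMSO (76 adjusted over the list alone, median -1.16, adjusted p = 1.18e-54, adjusted p = 0.0285 with an estimated correlation). In cytosolic RNA 0 were called lower and 1 higher. The cytosolic median of this list was 0.25 (0 adjusted over the list alone, adjusted p = 0.00268), but adjusted p = 0.719 with an estimated correlation. RPL7, a large subunit protein gene (chromosome 8: 74202506-74208024), stood at 1280 ± 164 CPM in polysomes with DMSO and 321 ± 45.1 CPM in those of starved cells, against 983 ± 88.8 and 1310 ± 174 CPM in cytosol. Its polysome association changed by a log2 value of -2.40 (95% interval -2.83 to -1.97; adjusted p = 4.44e-10). RPS18 (-2.25, SE 0.28), RPL18A (-2.24, SE 0.32), RPS19 (-2.23, SE 0.33) and RPL27A (-2.19, SE 0.29) were also lower, and RPS6, whose protein is the substrate of S6 kinase, changed by -1.63 (SE 0.21).

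Across the list, 62 of 78 ribosomal protein mRNAs had lower polysome association in starved cells (76 adjusted over the list alone, median -1.35, adjusted p = 5.46e-162, adjusted p = 0.00022 with an estimated correlation). Other TOP mRNAs, which begin with the same pyrimidine tract and encode translation factors and related proteins, were lower in 9 of 18 cases (16 adjusted over the list alone, median -0.89, adjusted p = 1.27e-31, adjusted p = 1.04e-06 with an estimated correlation). They included the elongation factor genes EEF1A1 (-1.92, SE 0.25; chromosome 6: 74225473-74233520), EEF1D (-1.85, SE 0.32) and EEF1B2 (-1.33, SE 0.22) and the initiation factor gene EIF3F (-1.37, SE 0.23). EEF1A1 levels in polysomes were 1770 ± 368 CPM with DMSO and 602 ± 99.4 CPM in starved cells. EEF2, the translocation factor, was at -1.19 (adjusted p = 0.0317), a call lost under 10 alternative settings, and TPT1 (-0.81, adjusted p = 0.138) and PABPC1 (-0.82, adjusted p = 0.208) missed the threshold. The eIF4E-sensitive list did not pass against other genes (1 of 20 lower, also adjusted over the list alone, median 0.14, mean -0.31, adjusted p = 0.913). Its polysome minus cytosolic score was 0.16 ± 0.10 with DMSO and 0.092 ± 0.22 in starved cells. A lower loading of this list is not excluded here or with the inhibitors, and changes are relative to the average mRNA.

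For polysome association in starvation, 200 genes were called by edgeR's interaction test, 195 lower and 5 higher. Regression on cytosolic RNA gave another balance, 461 higher and 566 lower. Of the 195, 191 were also called lower in polysome RNA, while 0 were called lower and 9 higher in cytosolic RNA. Pseudogenes made up 112 of the 195, and 71 belonged to the ribosomal protein or other TOP lists. Without DMSO replicate 2 the count was 125, and without the 4 doubted cultures 184. In polysome RNA 4129 genes were called, 2000 higher and 2129 lower, but 3885 higher and 1248 lower with scaling by library size only, which brought the median of all genes from 0.032 to 0.338 in polysome RNA, from 0.041 to 0.284 in polysome association and from 0.043 to 0.105 in cytosolic RNA. The lower polysome association of both TOP lists was kept under that scaling.

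**Figure D1:**
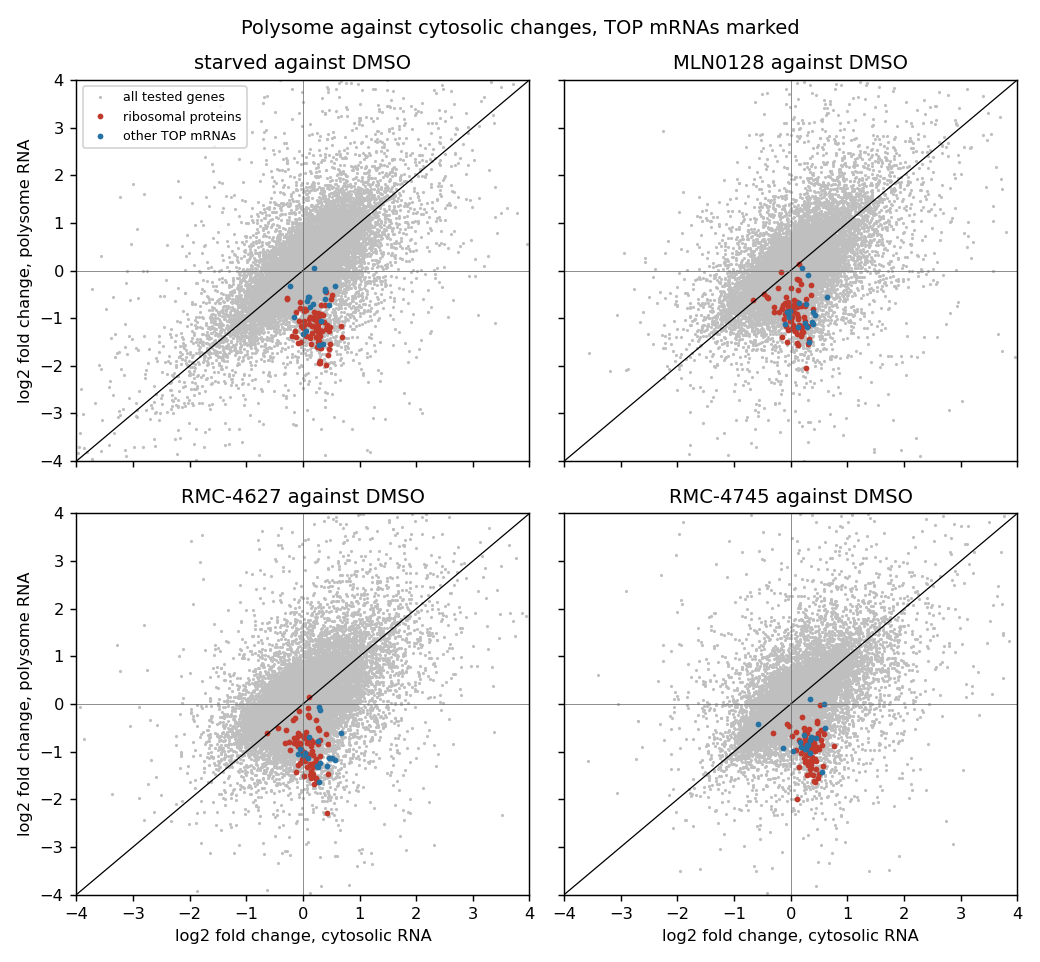
Log2 change in polysome RNA against log2 change in cytosolic RNA for each of 4 treatments compared with DMSO (1 point per gene, ribosomal protein and other TOP mRNAs in colour, line of equal change drawn, axes limited to -4 to 4 so that points outside are not shown). Of 78 ribosomal protein mRNAs, 78, 76, 76 and 78 lie below the line, with median changes in polysome association of -1.35, -0.90, -0.99 and -1.25 for starvation, MLN0128, RMC-4627 and RMC-4745.

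MLN0128, given together with serum, raised FOXO targets in cytosolic RNA and lowered genes of S phase and of ribosome assembly. RASD1, a Ras-related gene induced by steroid hormone (chromosome 17: 17397751-17399709), rose from 14.1 ± 3.5 to 107 ± 19.7 CPM (log2 change 2.92, SE 0.28; adjusted p = 1.2e-09), and TXNIP changed by 2.62 (SE 0.17). Among called genes of at least 10 CPM whose replicate values did not overlap, the highest also included CYP24A1, the vitamin D hydroxylase gene (2.43, SE 0.47), and the transcription factor genes KLF7 (2.12, SE 0.35) and EGR1 (2.11, SE 0.32). The lowest within this limit were RN7SL1, the signal recognition particle RNA (-2.22, SE 0.35), GNB1L (-2.19, SE 0.28), the fructokinase gene KHK (-2.02, SE 0.23), UHRF1, which maintains DNA methylation (-1.94, SE 0.34), and SDF2L1, an endoplasmic reticulum gene (-1.79, SE 0.26).

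Under MLN0128, 14 of 22 FOXO targets rose (16 adjusted over the list alone, median 1.06, adjusted p = 6.26e-20, adjusted p = 2.33e-05 with an estimated correlation). They included KLHL24 (3.47, SE 0.32), CCNG2 (2.45, SE 0.32) and HBP1 (2.07, SE 0.22). IRS2, an insulin receptor substrate gene under FOXO control, rose by 1.82 (SE 0.27) and CDKN1B by 1.13 (SE 0.21), while ERBB3 was at 0.21 (adjusted p = 0.473). E2F and S phase genes fell in 28 of 36 cases (29 adjusted over the list alone, median -0.95, adjusted p = 5.08e-29, adjusted p = 0.000958 with an estimated correlation). E2F2 was at -2.08 (SE 0.29), the phosphatase gene CDC25A at -1.98 (SE 0.29) and CDC6 at -1.77 (SE 0.22). Ribosome biogenesis factors fell in 19 of 45 cases (23 lower and 1 higher adjusted over the list alone, median -0.51, adjusted p = 1.62e-13, adjusted p = 0.00452 with an estimated correlation). NOP16 was at -1.21 and NOP56 at -1.05. Cholesterol synthesis genes fell in 6 of 25 cases (7 adjusted over the list alone, median -0.32, adjusted p = 0.000756, adjusted p = 0.0395 with an estimated correlation). Of 31 serum response genes 9 rose (10 adjusted over the list alone, median 0.46, adjusted p = 2.76e-08), but adjusted p = 0.0714 with an estimated correlation. The ERK phosphatase gene DUSP6 rose by 2.42 (SE 0.25) and KLF10 by 1.03 (SE 0.16). MYC was higher by 1.04 (adjusted p = 2.51e-05) and CCND1, cyclin D1, was at -0.32 (adjusted p = 0.521).

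edgeR called 1891 genes in cytosolic RNA with MLN0128, 815 higher and 1076 lower. The count fell to 1130 without DMSO replicate 1, to 1184 without MLN0128 replicate 2 and to 921 (467 higher, 454 lower) without the 4 doubted cultures.

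MLN0128 lowered the polysome association of 32 of 78 ribosomal protein mRNAs (61 adjusted over the list alone, median -0.90, adjusted p = 4.74e-81, adjusted p = 0.0167 with an estimated correlation) and of 13 of 18 other TOP mRNAs (16 adjusted over the list alone, median -1.12, adjusted p = 1.6e-42, adjusted p = 5.36e-08 with an estimated correlation). RPL7 changed by -2.31 (SE 0.21; adjusted p = 1.37e-09), at 308 ± 30.1 CPM in polysomes and 1180 ± 184 CPM in cytosol. Also lower were RPS4X (-1.85, SE 0.22), RPL31 (-1.82, SE 0.28), EEF1A1 (-1.82, SE 0.25) and RPS3A (-1.75, SE 0.28), and RPS6 was at -1.56 (SE 0.21). Among the other TOP mRNAs were HNRNPA1, a splicing factor gene (-1.50, SE 0.25), the poly(A)-binding protein gene PABPC1 (-1.36, adjusted p = 0.00329), and the initiation factor genes EIF3H (-1.26, SE 0.22) and EIF4B (-1.21, SE 0.21), the last 2 lost in the regression on cytosolic RNA. TPT1 (-0.81, adjusted p = 0.186) and EEF2 (-0.39, adjusted p = 0.821) missed the threshold. The eIF4E-sensitive list did not pass against other genes (0 of 20 called, 1 lower adjusted over the list alone, adjusted p = 0.8), and its median of 0.041 and its mean of -0.37 differed in sign. Its score was 0.025 ± 0.14, against 0.16 ± 0.10 with DMSO.

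With MLN0128, 124 genes changed in polysome association by edgeR's interaction test, 119 lower and 5 higher, while regression on cytosolic RNA gave 282 lower and 129 higher. Of the 119, 117 were also called lower in polysome RNA. In cytosolic RNA 0 of the 119 were called lower and 4 higher, and 60 of the 119 were pseudogenes and 45 members of the TOP lists. The count rested on several single cultures: 65 without DMSO replicate 2, 79 without DMSO replicate 3, 74 without DMSO replicate 4, 65 without MLN0128 replicate 1 and 71 without MLN0128 replicate 3, against 142 without the 4 doubted cultures. In polysome RNA, 66 of 78 ribosomal protein mRNAs were lower (69 adjusted over the list alone, median -0.86, adjusted p = 8.98e-50, adjusted p = 0.0411 with an estimated correlation), and 11 of 13 mitochondrial-encoded mRNAs were higher (13 adjusted over the list alone, median 0.80, adjusted p = 9.25e-09), but adjusted p = 0.153 with an estimated correlation. MT-CO1, a cytochrome oxidase subunit gene, was at 0.86 (SE 0.20; adjusted p = 0.00262). Polysome RNA had 2403 called genes, 1114 higher and 1289 lower, and 1407 higher and 984 lower with scaling by library size only.

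RMC-4627 at 3 nM raised RASD1, CYP24A1, TXNIP, KLF7 and EGR1 in cytosolic RNA and lowered S phase genes. RASD1 reached 88.9 ± 26.8 CPM (log2 change 2.65, SE 0.28; adjusted p = 1.24e-08), CYP24A1 changed by 2.68 (SE 0.47), TXNIP by 2.56 (SE 0.17), KLF7 by 1.90 (SE 0.34) and EGR1 by 1.89 (SE 0.31). UHRF1 (chromosome 19: 4903092-4962165) fell from 65.2 ± 12.7 to 13.8 ± 2.17 CPM (-2.24, SE 0.34; adjusted p = 1.85e-05), beside RN7SL1 (-2.25, SE 0.35), GNB1L (-2.14, SE 0.28), KHK (-1.91, SE 0.23) and CDC6 (-1.88, SE 0.22). E2F and S phase genes fell in 29 of 36 cases (31 adjusted over the list alone, median -1.01, adjusted p = 3.45e-32, adjusted p = 0.00054 with an estimated correlation). Lower members included ORC6 (-1.50, SE 0.23) and GINS1, a replicative helicase subunit gene (-1.36, SE 0.18). FOXO targets rose in 10 of 22 cases (14 adjusted over the list alone, median 0.89, adjusted p = 2.23e-14, adjusted p = 0.000238 with an estimated correlation). KLHL24 rose by 2.62 (SE 0.32), CCNG2 by 2.08 (SE 0.32) and BCL6 by 1.56 (SE 0.22). IRS2 rose by 1.49 (adjusted p = 0.000213) and CDKN1B by 1.12 (SE 0.21), CCND1 was lower at -0.94 (adjusted p = 0.0182, lost under 4 alternative settings), and ERBB3 was at -0.11 (adjusted p = 0.74).

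Ribosome biogenesis factors fell with RMC-4627 in 15 of 45 cases (18 adjusted over the list alone, median -0.46, adjusted p = 1.2e-09, adjusted p = 0.0253 with an estimated correlation). Here NOP16 was at -1.05 and NOP56 at -0.83. Serum response genes rose in 8 of 31 cases (8 adjusted over the list alone, median 0.23, adjusted p = 2.07e-05), but adjusted p = 0.158 with an estimated correlation. DUSP6 rose by 2.44 (SE 0.25) and KLF10 by 1.07 (SE 0.16). Cholesterol synthesis genes fell in 6 of 25 cases (9 lower and 1 higher adjusted over the list alone, median -0.30, adjusted p = 0.00341), but adjusted p = 0.101 with an estimated correlation. The edgeR count in cytosolic RNA was 1802 genes, 720 higher and 1082 lower, and it was 1118 without DMSO replicate 1 and 1330 without the 4 doubted cultures.

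Polysome association with RMC-4627 was lower for 37 of 78 ribosomal protein mRNAs (63 adjusted over the list alone, median -0.99, adjusted p = 1.15e-67, adjusted p = 0.0369 with an estimated correlation) and for 14 of 18 other TOP mRNAs (16 adjusted over the list alone, median -1.25, adjusted p = 2e-39, adjusted p = 9.37e-08 with an estimated correlation). RPL7 changed by -2.71 (95% interval -3.15 to -2.28; adjusted p = 8.83e-12), at 261 ± 54.9 CPM in polysomes and 1320 ± 94.2 CPM in cytosol. EEF1A1 (-1.93, SE 0.25), RPS3A (-1.91, SE 0.28), RPL31 (-1.88, SE 0.28) and RPS18 (-1.88, SE 0.28) were also lower, as were RPS6 (-1.81, SE 0.22), RPS4X (-1.79, SE 0.22) and RPL6 (-1.49, SE 0.20). HNRNPA1 (-1.73, SE 0.25), PABPC1 (-1.65, adjusted p = 0.00013), EIF3H (-1.58, SE 0.22) and EIF4B (-1.27, SE 0.21) fell among the other TOP mRNAs, the last 2 not in the regression on cytosolic RNA. TPT1 was at -0.97 (adjusted p = 0.036), a call lost under 8 alternative settings, and EEF2 at -0.43 (adjusted p = 0.538). The eIF4E-sensitive list did not pass against other genes (0 of 20 called, 0 adjusted over the list alone, median 0.20, mean -0.25, camera direction lower, adjusted p = 0.832). Its score was 0.084 ± 0.13, against 0.16 ± 0.10 with DMSO.

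Higher polysome association with RMC-4627 was found for MT-ATP8, an ATP synthase subunit gene of mitochondrial DNA (1.37, adjusted p = 0.0453), DVL3, a Wnt signalling gene (1.16, adjusted p = 0.0279), KIAA0100 (1.00, adjusted p = 0.0169), KLHL36 (0.90, adjusted p = 0.0461) and KIAA1191 (0.85, adjusted p = 0.0174), each lost under 6 to 11 alternative settings. In polysome RNA all 13 mitochondrial-encoded mRNAs were higher (13 adjusted over the list alone, median 1.14, adjusted p = 3.36e-14), but adjusted p = 0.0528 with an estimated correlation. MT-CO1 was at 1.13 (SE 0.20) and MT-ATP8 at 1.54 (SE 0.26). In the same RNA 66 of 78 ribosomal protein mRNAs were lower (70 adjusted over the list alone, median -0.89, adjusted p = 8.68e-48, adjusted p = 0.047 with an estimated correlation).

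In polysome association edgeR called 178 genes with RMC-4627, 170 lower and 8 higher. Higher genes were more frequent in fits that link both RNAs of a culture, the block by culture (71 higher, 320 lower) and limma on ratios (61 and 248). The regression on cytosolic RNA also gave more (477 and 733). The main fit ignored that link, so the small share of higher genes depends on the fit. Of the 170, 162 of the 170 were called lower in polysome RNA. In cytosolic RNA 0 of the 170 were lower and 12 higher, and 80 of them were pseudogenes and 51 TOP list members. Without DMSO replicate 2 the count was 105, without RMC-4627 replicate 3 it was 292, and without the 4 doubted cultures 194. In polysome RNA 3032 genes were called, 1325 higher and 1707 lower, and 1556 higher and 1283 lower with scaling by library size only.

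RMC-4745 at 35 nM raised RASD1 to 106 ± 36.4 CPM in cytosolic RNA (log2 change 2.91, SE 0.28; adjusted p = 1.82e-09), with CYP24A1 at 2.62 (SE 0.47), TXNIP at 2.51 (SE 0.17), SLC2A4, the insulin-responsive glucose transporter gene, at 1.92 (SE 0.30) and EGR1 at 1.90 (SE 0.31). The lowest changes among called genes of at least 10 CPM whose replicate values did not overlap were those of MCM10 (-1.80, SE 0.33), FAM111B (-1.74, SE 0.34), CLSPN, a replication checkpoint gene (-1.60, SE 0.32), and UHRF1 (-1.54, SE 0.34), followed by GNB1L (-1.53, SE 0.27). E2F and S phase genes fell in 20 of 36 cases (27 adjusted over the list alone, median -0.72, adjusted p = 3.53e-27, adjusted p = 0.00162 with an estimated correlation). Members included CDC25A (-1.68, SE 0.29), the cyclin gene CCNE2 (-1.53, SE 0.29) and CDC6 (-1.38, SE 0.22). FOXO targets rose in 11 of 22 cases (13 adjusted over the list alone, median 0.68, adjusted p = 3.44e-11, adjusted p = 0.00157 with an estimated correlation). These included KLHL24 (2.00, SE 0.31), BCL6 (1.51, SE 0.22), IRS2 (1.45, SE 0.27) and HBP1 (1.13, SE 0.22), and CDKN1B rose by 1.00 (SE 0.21). ERBB3 was at 0.18 (adjusted p = 0.607).

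Serum response genes rose with RMC-4745 in 7 of 31 cases (11 adjusted over the list alone, median 0.63, adjusted p = 4.55e-11, adjusted p = 0.0342 with an estimated correlation). DUSP6 was at 2.40 (SE 0.25) and KLF10 at 0.95 (SE 0.16). Ribosome biogenesis factors fell in 8 of 45 cases (15 lower and 1 higher adjusted over the list alone, median -0.46, adjusted p = 4.12e-12, adjusted p = 0.00785 with an estimated correlation). POLR3G, an RNA polymerase III subunit gene, was at -1.25 (SE 0.23) and NOP16 at -0.76 (SE 0.16). Of 25 cholesterol synthesis genes 0 were called by edgeR (0 adjusted over the list alone, median -0.0886, adjusted p = 0.182). Cytosolic ribosomal protein mRNAs had a median of 0.34, with 4 of 78 higher (4 adjusted over the list alone, adjusted p = 3.36e-08), but adjusted p = 0.404 with an estimated correlation. edgeR called 927 genes in cytosolic RNA, 594 higher and 333 lower, against 474 higher and 549 lower with scaling by library size only. The count was 549 without RMC-4745 replicate 3, 550 without DMSO replicate 2, 558 without DMSO replicate 3 and 524 without the 4 doubted cultures.

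RMC-4745 lowered the polysome association of 51 of 78 ribosomal protein mRNAs (73 adjusted over the list alone, median -1.25, adjusted p = 5.49e-175, adjusted p = 0.000135 with an estimated correlation) and of 12 of 18 other TOP mRNAs (15 adjusted over the list alone, median -1.08, adjusted p = 2.23e-44, adjusted p = 2.6e-08 with an estimated correlation). RPL7 changed by -2.11 (SE 0.21; adjusted p = 2.28e-08), at 318 ± 45.1 CPM in polysomes and 1060 ± 103 CPM in cytosol, beside RPL27A (-2.06, SE 0.29), RPL31 (-2.03, SE 0.28), RPS18 (-2.03, SE 0.28), EEF1A1 (-1.97, SE 0.25), RPS4X (-1.96, SE 0.22) and RPS6 (-1.70, SE 0.22). Among the other TOP mRNAs, EEF1B2 (-1.22, SE 0.22), EIF4B (-1.11, SE 0.20; lost in the regression on cytosolic RNA) and EIF3L (-1.10, SE 0.20) were lower, and TPT1 at -1.07 (adjusted p = 0.0139) lost its call under 7 alternative settings. PABPC1 (-0.90, adjusted p = 0.121) and EEF2 (-0.60, adjusted p = 1) missed the threshold. The eIF4E-sensitive list did not pass against other genes (0 of 20 called, 0 adjusted over the list alone, median -0.019, mean -0.34, adjusted p = 0.728). Its score was 0.0072 ± 0.065, against 0.16 ± 0.10 with DMSO.

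With RMC-4745, 182 genes changed in polysome association, 178 lower and 4 higher by edgeR, while regression on cytosolic RNA gave 188 lower and 58 higher. Of the 178, 173 were called lower in polysome RNA. In cytosolic RNA 0 of the 178 were lower and 12 higher, and 101 of them were pseudogenes and 63 TOP list members. The count was 96 without RMC-4745 replicate 3, 101 without DMSO replicate 2 and 151 without the 4 doubted cultures. In polysome RNA 65 of 78 ribosomal protein mRNAs were lower (72 adjusted over the list alone, median -0.91, adjusted p = 1.97e-65, adjusted p = 0.0171 with an estimated correlation). There, 9 of 13 mitochondrial-encoded mRNAs were higher (13 adjusted over the list alone, median 0.83, adjusted p = 5.01e-09), but adjusted p = 0.164 with an estimated correlation. MT-CO1 was at 1.00 (SE 0.20). Polysome RNA had 1676 called genes, 781 higher and 895 lower, and 1066 higher and 691 lower with scaling by library size only.

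**Figure D2:**
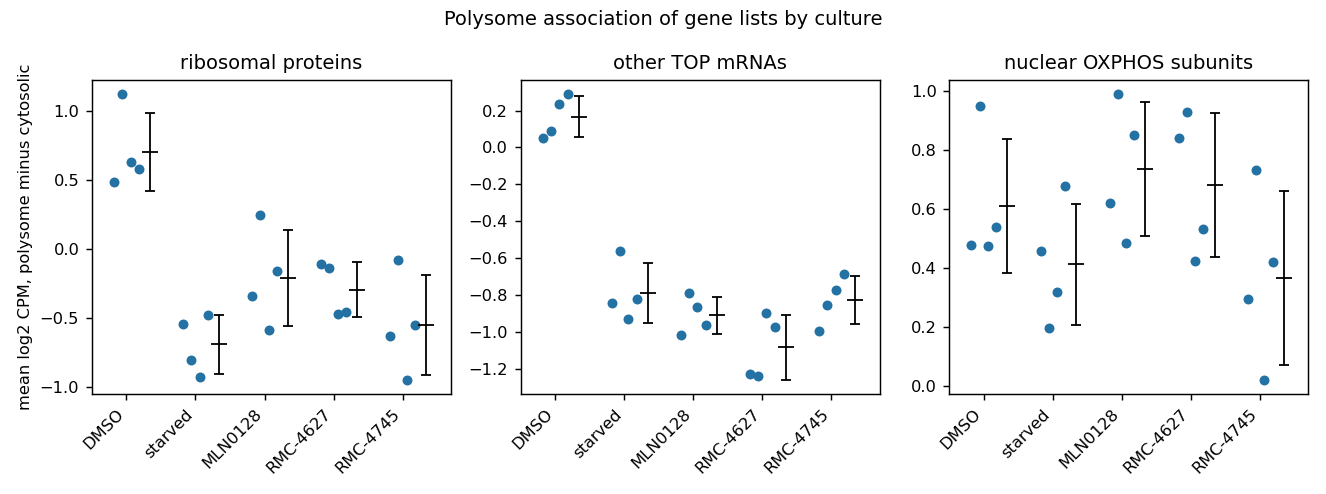
Mean log2 ratio of polysome to cytosolic CPM over the members of a gene list, per culture (dots, n = 4) with mean and SD (bars), in each of 5 conditions, with vertical axes that differ between panels and do not start at 0. The ribosomal protein score was 0.70 ± 0.29 with DMSO and -0.69 ± 0.21 in starved cells. With the inhibitors it lay between, at -0.21 ± 0.35 (MLN0128), -0.30 ± 0.20 (RMC-4627) and -0.55 ± 0.36 (RMC-4745). In direct contrasts of starved cells with these inhibitors, 0 of 78 members were called (camera adjusted p = 6.86e-12, 3.05e-06 and 0.00672, but 0.813, 0.848 and 0.995 with an estimated correlation). The other TOP score was less low in starved cells (-0.79 ± 0.16) than with the inhibitors (-0.91 ± 0.10, -1.08 ± 0.17 and -0.83 ± 0.13).

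Lower polysome association was shared by 92 genes among the 3 inhibitors, of which 31 were ribosomal protein genes, 9 were other TOP genes and 46 were pseudogenes. Among the 16976 tested genes 1654 were pseudogenes. Where such copies take up fragments of their parent genes, the counts and overlaps hold the same signal more than once. Also lower in starved cells were 81 of the 92. Since all treatments were set against the same DMSO libraries, overlaps may arise in part from those libraries. MLN0128 and RMC-4627 shared 106 lower genes, where independent lists would share 1.19, simulated unchanged groups against the same controls shared 0 and split controls gave 31, out of shorter lists of 33 and 76. For RMC-4627 and RMC-4745 these values were 119, 1.78, 0 and 42 (of 57 and 57), and for MLN0128 and RMC-4745 they were 102, 1.25, 0 and 31 (of 33 and 57). The simulated 0 was fixed by the design, because unchanged groups yield hardly any calls, so it does not show what shared controls add. Split controls used DMSO replicates 1 and 2 for the first-named inhibitor and 3 and 4 for the second. Polysome libraries also differed along that line and the lists were shorter, so the split counts do not measure the effect of shared controls.

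Compared directly, the 3 inhibitors did not differ in any single gene past the threshold by edgeR, although the doses of 3, 35 and 40 nM differ. Other edgeR settings did call some: between RMC-4627 and RMC-4745, 214 in polysome association (208 lower), 20 in polysome RNA and 8 in cytosolic RNA without the count filter. For the same pair, 12 were called in polysome association with the block by culture and 28 in cytosolic RNA with the replicate number as a block. Between RMC-4745 and MLN0128, 13 were called in cytosolic RNA without the count filter. Between RMC-4627 and MLN0128, 0 genes were called in cytosolic RNA, polysome RNA and polysome association (210, 827 and 404 at unadjusted p under 0.05), and DESeq2 called 0 in each. Between RMC-4745 and MLN0128, 0 were called (1524, 611 and 911 at unadjusted p under 0.05), while DESeq2 called 1, 1 and 0. Between RMC-4627 and RMC-4745, 0 were called (1377, 1092 and 1755 at unadjusted p under 0.05), while DESeq2 called 1, 5 and 2. The 95% interval of the cytosolic difference lay within a 2-fold change for 65.8%, 57.2% and 56.9% of genes in these 3 pairs, and that of polysome association for 43.6%, 35.5% and 30.3%, so larger differences remain possible for the rest.

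The list score of ribosomal protein polysome association differed between RMC-4745 and MLN0128 by -0.34 (95% interval -0.74 to 0.056). It differed by -0.086 (-0.48 to 0.31) between RMC-4627 and MLN0128, and by 0.26 (-0.14 to 0.65) between RMC-4627 and RMC-4745. These 3 limma intervals were fitted without a block and do not settle whether the compounds differ. With the replicate number as a block, the interval of RMC-4745 against MLN0128 lay wholly on the lower side. Its adjusted p over the lists did not pass, as given in the section on processing. For the other TOP mRNAs the differences without a block, in the same order of pairs, were 0.082 (-0.13 to 0.30), -0.18 (-0.39 to 0.039) and -0.26 (-0.47 to -0.043). The last did not pass (limma adjusted p = 0.205, exact permutation p = 0.0857). EEF2 polysome association differed by -0.22 (95% interval -0.83 to 0.40) between RMC-4745 and MLN0128, by -0.039 (-0.65 to 0.58) between RMC-4627 and MLN0128 and by 0.18 (-0.44 to 0.79) between RMC-4627 and RMC-4745.

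FOXO targets were less high in cytosolic RNA with RMC-4745 than with MLN0128 (median log2 difference -0.34; adjusted p = 1.93e-07, adjusted p = 0.022 with an estimated correlation; 0 of 22 called by edgeR over all genes, 3 lower adjusted over the list alone). This was the only list of 252 list comparisons between inhibitors, counted over 3 pairs and 3 readouts, that passed with both correlations, and the requirement of both was set after the results were seen. KLHL24 differed by -1.47 (95% interval -2.06 to -0.88; adjusted p = 0.169), HBP1 by -0.94 (-1.38 to -0.50) and CCNG2 by -0.95 (-1.56 to -0.34). As a score over the list, FOXO targets stood at 2.77 ± 0.19 with DMSO, 3.98 ± 0.23 with MLN0128, 3.75 ± 0.067 with RMC-4627 and 3.52 ± 0.031 with RMC-4745 (mean log2 CPM ± SD, n = 4). The score with RMC-4745 was lower than that with MLN0128 by -0.46 (95% interval -0.70 to -0.22; limma adjusted p = 0.0173, exact two-sided permutation p = 0.0286, the smallest that 4 against 4 allows). MLN0128 replicate 2, a doubted culture, raised that mean at 4.3, while the other replicates lay at 3.766 to 3.966 and RMC-4745 reached at most 3.557. The score uses the same data that singled out this list, so it is not separate support.

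**Figure D3:**
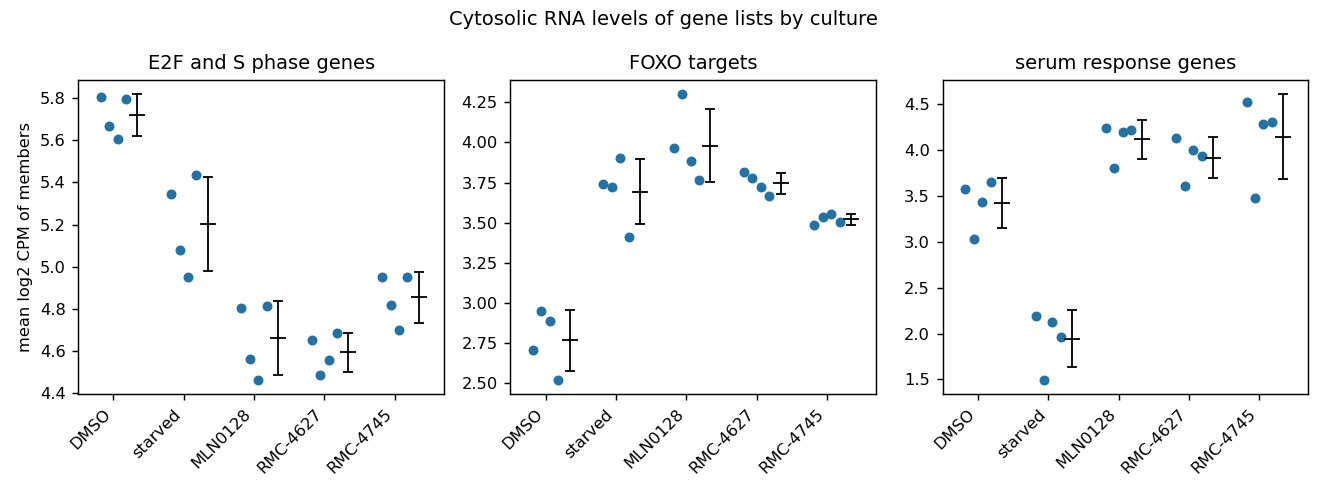
Mean log2 CPM in cytosolic RNA over the members of a gene list, per culture (dots, n = 4) with mean and SD (bars), in each of 5 conditions, with vertical axes that differ between panels and do not start at 0. The serum response score was 1.94 ± 0.31 in starved cells, 3.42 ± 0.28 with DMSO and between 3.92 ± 0.22 and 4.14 ± 0.46 with the inhibitors.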

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

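The counts over other splits of the cultures, the test of ribosomal protein mRNA levels in polysomes and the contrasts of starvation with each inhibitor were chosen only after the results were seen.

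Polysome association differed from cytosolic change for 200 genes in starvation, 124 with MLN0128, 178 with RMC-4627 and 182 with RMC-4745 by edgeR's interaction test, among them 62, 32, 37 and 51 of 78 ribosomal protein mRNAs, all lower. The length of a gene's annotated exons and its abundance are argued against as the whole cause: over 10000 lists of other genes matched on both, the lowest median in any treatment was -0.264, while the ribosomal protein medians lay between -1.35 and -0.90. That length had a median of 2896.5 bases among the members. The lengths of the mRNA and its coding sequence were not matched, so they were not tested as a cause. Fragments shared with a pseudogene named after the member are argued against as the whole cause too. The 25 members with no such tested pseudogene had a median of at most -0.745 in each treatment, against -1.43 to -0.993 for the 53 members with one. Pseudogenes with clone names were not matched to members, so some of the 25 may have a tested copy, and sharing with those was not tested. A change of the cytosolic level alone is excluded because the polysome levels themselves fell, with a weakest median of -0.862. A lower loading of TOP mRNAs on ribosomes under mTOR inhibition and starvation stays as a hypothesis, found and tested on the same data, and lighter fractions were not measured.

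The list of FOXO targets differed between inhibitors in cytosolic RNA, with a median log2 difference of -0.343 between RMC-4745 and MLN0128. Serum response genes were lower in starved cells than with each inhibitor, with median log2 differences of -1.88 against MLN0128 (23 of 31 lower), -1.68 against RMC-4627 (20 lower, 1 higher) and -2.04 against RMC-4745 (24 lower), and each passed with both correlations (adjusted p = 5.63e-06, 2.2e-05 and 1.43e-05 with an estimated correlation).

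Of 120 sets of replicate values examined for a library far from the others, 3 had one, where chance gives about 1 in 20 sets, or 6.0 here. A polysome file of starved cells held 32415621 counts, against 20084545 to 22114021 in the other files of that group. ACTG2 with MLN0128 stood at 385.69 CPM in 1 cytosolic library and at 452.19 to 464.65 CPM in the others. UHRF1 with RMC-4745 stood at 32.409 CPM in 1 polysome library and at 13.813 to 16.196 CPM in the others.

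Other groupings of the same 8 cultures, 4 per condition, were fitted to see whether chance could give as many calls, with only those cultures in each fit. In starvation the real split called 2050 genes in cytosolic RNA, 3713 in polysome RNA and 170 in polysome association, and the highest of the 34 other splits called 0, 1 and 0. For MLN0128 the real values were 2172, 2667 and 126, and the highest others 0, 3 and 0. For RMC-4627 they were 1944, 3159 and 222 against 0, 4 and 0, and for RMC-4745 809, 1589 and 143 against 0, 605 and 0. In these 12 comparisons the real split was the highest, 1 of 35, which is the smallest share 8 cultures allow. This argues against chance, but the comparisons share the DMSO libraries and the splits ignore the replicate numbers. For polysome against cytosolic RNA in DMSO (7202 genes, highest other split 0) the 8 libraries come from 4 cultures, so its splits are not of independent samples and nothing is drawn from them. In the 9 comparisons between inhibitors the real split called 0 genes, so all 35 splits were as high by construction and say nothing about chance there. Some other splits called more: up to 9, 762 and 90 for RMC-4627 with MLN0128, 1, 26 and 0 for RMC-4745 with MLN0128, and 68, 209 and 173 for RMC-4627 with RMC-4745 (cytosolic RNA, polysome RNA, polysome association).

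A structure of the samples may lie behind those splits, since 605, 762, 26, 209, 9 and 1 came from setting replicates 1 and 2 against replicates 3 and 4, though 90, 68 and 173 came from RMC-4627 replicates 1, 2 and 4 with replicate 2 of the other inhibitor, and replicate numbers may mark batches that the labels do not name. Fitted over all polysome libraries, 2104 genes differed between replicates 1 and 2 and replicates 3 and 4 (910 higher and 1194 lower in 3 and 4), and 473 did so in cytosolic RNA. Greater depth of the summed replicate 1 is argued against, because 1240 genes were still called with only technical replicate 1A and 2831 with only 1B. A trend with gene length is argued against as well, with 2108 genes called after each library's trend was removed. The number is spread evenly over the conditions, so it does not part treated from control libraries, and no biological explanation was tested.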

How the results depend on the processing

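The fit without 4 doubted cultures, the fit without mitochondrial genes and the list scores with the replicate number as a block were chosen only after the results were seen.

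Of 194 gene results 166 were the same under all settings, 20 lost their call under at least 1 and 2 changed sign, and of 143 list results 52 were the same under all, 91 lost their call with the estimated correlation or another setting and 0 changed sign. EEF2 polysome association between RMC-4627 and MLN0128 changed sign to 0.0318 without the 4 doubted cultures and to 0.033, 0.00271 and 0.0483 with 1 culture left out (range -0.172 to 0.0483), and between RMC-4627 and RMC-4745 to -0.0173 with library size only, all close to 0. Replicate numbers were shared between groups (mean r of libraries with the same number 0.127 in cytosolic and 0.124 in polysome RNA, 21 of 40 pairs above 0.1 in each). For other numbers the mean r was -0.0424 and -0.0412. On average, 17 of 20 cytosolic and 15 of 20 polysome libraries correlated best with libraries of their own number. These values go with a batch shared by number, which the main fit ignored, although not every same-number pair correlated. The number was not taken as a pairing, and its block is an alternative fit. With it, the limma score of ribosomal protein polysome association was lower with RMC-4745 than with MLN0128 by -0.341 (95% interval -0.64 to -0.0429, adjusted p = 0.192 over 28 lists; same-number differences -0.391 to -0.293), an interval that included 0 without the block. Of the list scores between inhibitors 5 then passed, all in cytosolic RNA, against 1 without it. Cytosolic and polysome libraries of the same culture also correlated (mean r 0.13, against -0.0435 for other numbers of that condition, 11 of 20 best with their own). The main fit ignored that link too. With the block by culture, 232 genes changed in polysome association in starvation (14 higher), 151 with MLN0128 (4 higher) and 391 with RMC-4627 (71 higher). Without mitochondrial genes every count stayed within 1.5 times. The cause was not tested. In simulated counts edgeR recovered 13.4% of 2-fold changes in polysome association with RMC-4627.

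Counts moved as follows. Regression on cytosolic RNA gave about 1.0e3 genes in polysome association in starvation, 411 with MLN0128 (129 higher, 282 lower) and 1210 with RMC-4627, and for RMC-4627 limma on ratios gave 309, no filter 320, DESeq2 325, the replicate block 487 (129 higher, 358 lower) and the block by culture 391. The replicate block gave 2939 (MLN0128), 2971 (RMC-4627) and 1682 (RMC-4745) in cytosolic RNA and 2670 (RMC-4745) in polysome RNA. A fit of only the groups compared gave 2838 (MLN0128) and 2757 (RMC-4627) in cytosolic RNA, and the fit without the 4 doubted cultures gave 921 (MLN0128, 857 shared) and 524 (RMC-4745, 509 shared). Between RMC-4627 and MLN0128, no filter gave 1 in polysome RNA and 1 in polysome association, and the fit without the 4 doubted cultures 1 in polysome RNA. Between RMC-4745 and MLN0128, cytosolic RNA gave 13 (no filter), 1 (DESeq2) and 1 (replicate block), and polysome RNA 1 (DESeq2). Between RMC-4627 and RMC-4745, cytosolic RNA gave 8 (no filter), 1 (DESeq2) and 28 (replicate block), polysome RNA 20, 5 and 4, and polysome association 214, 2 and 4, with 12 from the block by culture.

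With each culture left out in turn, the counts in cytosolic RNA, polysome RNA and polysome association ranged over 1811 to 2378, 3114 to 4446 and 125 to 199 (starvation), 1130 to 1623, 1797 to 2259 and 65 to 131 (MLN0128), 1118 to 1737, 2214 to 3128 and 105 to 292 (RMC-4627), and 549 to 824, 1173 to 1522 and 96 to 186 (RMC-4745). Between inhibitors they ranged from 0 to 1 in polysome RNA for RMC-4627 and for RMC-4745 against MLN0128, from 0 to 2 for RMC-4627 against RMC-4745, and were 0 otherwise, and polysome against cytosolic RNA in DMSO gave 4968 to 6014.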

Other observations

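Tests chosen only after the results were seen were the limma list scores, the contrasts of starvation with each inhibitor, both tests of mitochondrial-encoded mRNAs, and the choice of RASD1 in starvation and of ACTG2 with the inhibitors.

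Cytosolic mRNAs of amino acid and protein metabolism were lower in several treatments, but these calls rest on the preset correlation. Aminoacyl-tRNA synthetase genes, which charge tRNAs, were lower in 9, 10, 9 and 5 of 20 cases (11, 10, 10 and 7 adjusted over the list alone) in starvation, MLN0128, RMC-4627 and RMC-4745, with medians of -0.45, -0.36, -0.30 and -0.36 (adjusted p = 2.54e-05, 1.12e-06, 8.59e-05 and 5.2e-06; with an estimated correlation, adjusted p = 0.113, 0.0714, 0.158 and 0.117). MARS, the methionyl-tRNA synthetase gene, was at -1.12 (SE 0.17) in starvation, -1.28 (SE 0.17) with MLN0128 and -0.84 (SE 0.17) with RMC-4745. Mitochondrial ribosomal protein genes were lower in 10, 21, 12 and 1 of 76 cases, and 1 was higher with RMC-4745 (11, 26, 16 and 0 lower adjusted over the list alone), with medians of -0.19, -0.35, -0.32 and -0.18 (adjusted p = 0.00272, 4.42e-11, 1.47e-07 and 0.000344; with an estimated correlation, adjusted p = 0.551, 0.164, 0.231 and 0.404). MRPL36 stood at -0.85 (SE 0.19) in starvation and -1.14 (SE 0.19) with MLN0128. Proteasome genes were lower in 1, 8, 4 and 0 of 31 cases (0, 14, 13 and 0 adjusted over the list alone; adjusted p = 0.0205, 9.64e-07, 2.19e-05 and 0.000344; with an estimated correlation, adjusted p = 0.499, 0.16, 0.158 and 0.323). ATF4 targets, genes of the amino acid and stress response, were lower in 9, 6, 9 and 2 and higher in 1, 2, 1 and 1 of 30 cases (lower in 11, 7, 13 and 4 adjusted over the list alone; adjusted p = 0.00106, 0.00316, 0.0011 and 0.0468; with an estimated correlation, adjusted p = 0.113, 0.164, 0.158 and 0.386). The serine synthesis gene PSAT1 was at -1.08 (SE 0.20) in starvation and -1.05 (SE 0.20) with MLN0128, and the amino acid transporter gene SLC38A2 higher by 1.47 (SE 0.18) with MLN0128.

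Glycolysis and HIF1 genes were lower in 8, 6, 5 and 1 and higher in 2, 1, 1 and 0 of 32 cases (lower in 10, 12, 11 and 1 adjusted over the list alone; adjusted p = 0.00602, 0.000538, 0.000791 and 0.07; with an estimated correlation, adjusted p = 0.276, 0.164, 0.158 and 0.404). PFKFB3, a regulator of glycolysis, was at -1.55 (SE 0.195) in starvation. Nucleotide synthesis genes were lower in 6, 3, 3 and 1 of 22 cases (6, 5, 4 and 3 adjusted over the list alone; adjusted p = 0.000565, 0.00197, 0.00802 and 0.0514; with an estimated correlation, adjusted p = 0.113, 0.164, 0.231 and 0.386). Fatty acid synthesis genes were lower in 6 and higher in 1 of 13 cases in starvation (8 and 1 adjusted over the list alone; adjusted p = 0.000328), but adjusted p = 0.0825 with an estimated correlation. The desaturase gene SCD was at -0.9997 (SE 0.15). With MLN0128, RMC-4627 and RMC-4745 the list gave adjusted p = 0.218, 0.0449 and 0.241, and adjusted p = 0.52, 0.3 and 0.535 with an estimated correlation. Estrogen receptor targets were lower in 6 and higher in 2 of 22 cases in starvation (7 and 2 adjusted over the list alone; adjusted p = 0.00272), but adjusted p = 0.113 with an estimated correlation, and with the inhibitors the adjusted p was 0.713, 0.533 and 0.913. AREG, the amphiregulin growth factor gene in this list, was at -1.48 (SE 0.29) in starvation, 0.85 (SE 0.28) with MLN0128, a call lost under 7 alternative settings, and 1.20 (SE 0.28) with RMC-4745, lost under 1. Lysosome and autophagy genes were higher in 3 of 33 cases in starvation (3 adjusted over the list alone; adjusted p = 0.0481), but adjusted p = 0.377 with an estimated correlation, and gave adjusted p = 0.26, 0.294 and 0.104 with the inhibitors. The autophagy gene GABARAPL1 was higher by 2.28 (SE 0.32) in starvation, 2.62 (SE 0.32) with MLN0128 and 2.16 (SE 0.32) with RMC-4745. Of 30 genes of G2 and mitosis 1 was higher in starvation (1 adjusted over the list alone; adjusted p = 0.0269), but adjusted p = 0.668 with an estimated correlation, and the inhibitors gave adjusted p = 0.554, 0.469 and 0.837.

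Non-coding snoRNA hosts with TOP tracts were higher in cytosolic RNA in 4, 3, 4 and 6 and lower in 2, 1, 1 and 0 of 13 cases (higher in 5, 6, 5 and 8 adjusted over the list alone; adjusted p = 0.159, 0.0075, 0.00311 and 1.74e-05; with an estimated correlation, adjusted p = 0.719, 0.479, 0.419 and 0.316). SNHG8 (1.14, SE 0.19) and EPB41L4A-AS1 (1.39, SE 0.24) were higher with RMC-4745. Other TOP mRNAs had cytosolic medians of 0.18, 0.26, 0.28 and 0.29 with 1 of 18 higher in each treatment (1, 1, 4 and 4 adjusted over the list alone; adjusted p = 0.0481, 0.0232, 0.00349 and 0.00359; with an estimated correlation, adjusted p = 0.357, 0.293, 0.158 and 0.239). Nuclear-encoded respiratory chain mRNAs had 0 of 76 called in polysome association by edgeR (0 adjusted over the list alone), with medians of -0.22 in starvation (adjusted p = 0.000556) and -0.24 with RMC-4745 (adjusted p = 4.47e-06), but adjusted p = 0.971 and 0.76 with an estimated correlation. The score of this list was not lower with MLN0128 (0.74 ± 0.23) or RMC-4627 (0.68 ± 0.24) than with DMSO (0.61 ± 0.23). Past the threshold in no treatment in cytosolic RNA were mRNAs with upstream open reading frames (adjusted p = 0.0818, 0.389, 0.533 and 0.123), polyamine genes (0.254, 0.309, 0.641 and 0.724), mTOR pathway genes (0.917, 0.172, 0.0883 and 0.101), interferon genes (0.803, 0.435, 0.312 and 0.406), luminal epithelial genes (0.376, 0.458, 0.593 and 0.104), untranslated nuclear RNAs (0.874, 0.994, 0.976 and 0.631) and markers of other cell types (0.798, 0.994, 0.995 and 0.837).

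RASD1 stood at 0.75 ± 0.113 CPM in starved cytosol, 14.1 ± 3.5 CPM with DMSO and 88.9 ± 26.8 to 107 ± 19.7 CPM with the inhibitors, and ACTG2 at 2.76 ± 0.83 CPM, 242 ± 41.2 CPM and 439 ± 36 to 490 ± 89.4 CPM (n = 4). In direct contrasts, cholesterol synthesis genes were lower in starved cells than with MLN0128, RMC-4627 and RMC-4745 (medians -0.59, -0.52 and -0.88; 9, 10 and 17 of 25 lower, and 1 higher against RMC-4627; with an estimated correlation, adjusted p = 0.00206, 0.000707 and 1.43e-05), and so were ribosome biogenesis genes (medians -0.45, -0.54 and -0.60; 13, 22 and 24 of 45 lower; with an estimated correlation, adjusted p = 0.0488, 0.00965 and 0.0113). E2F and S phase genes were higher in starved cells than with the inhibitors in 9, 11 and 3 of 36 cases, but with an estimated correlation the adjusted p was 0.14, 0.118 and 0.488. In polysome association, 1, 284 and 1 genes differed between starved cells and cells given MLN0128, RMC-4627 and RMC-4745.

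Overlaps of cytosolic calls between treatments share the DMSO libraries. The simulated 0 was fixed by the design here too, and controls were split by the same replicate numbers, so neither value measures the effect of shared controls. MLN0128 and RMC-4627 shared 831 lower genes (68.6 for independent lists, 0 in simulated unchanged groups, 262 with split controls, out of shorter lists of 691 and 424). They shared 547 higher genes (34.6, 0 and 156), and 0 genes were called in opposite directions. Starvation and MLN0128 shared 525 lower genes (94.3, 0 and 201, the last with 381 genes in the shorter list). They shared 330 higher genes (43.1, 0 and 86), and 108 genes were called in opposite directions. The sizes of the lists with split controls were kept for lower genes only. Across genes, which are not independent replicates, cytosolic log2 changes correlated at r = 0.849 for MLN0128 with RMC-4627 and 0.417 for starvation with MLN0128. Simulated unchanged groups gave 0.499 and 0.506, and the covariance exceeded the simulated one by 0.295 and 0.132. With split controls r was 0.534 and 0.259. In polysome association, MLN0128 with RMC-4627 gave r = 0.66 (simulated 0.494). RMC-4745 gave 0.552 with MLN0128 and 0.544 with RMC-4627 (simulated 0.501 and 0.506). Starvation gave 0.439, 0.432 and 0.599 with MLN0128, RMC-4627 and RMC-4745 (simulated 0.501, 0.509 and 0.504). Apart from 0.66 and 0.599, these lay near what shared DMSO libraries alone gave.

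A pattern not foreseen was the rise of mRNAs encoded by mitochondrial DNA in polysome RNA with the inhibitors, which cytosolic ribosomes do not translate, although the list call was lost with each inhibitor (adjusted p = 0.153, 0.0528 and 0.164 with an estimated correlation). List scores rose by 0.838 (95% interval 0.308 to 1.37) with MLN0128, 1.18 (0.651 to 1.71) with RMC-4627 and 0.759 (0.229 to 1.29) with RMC-4745. A higher cytosolic level could account for part of it, since the lowest lower bound of the change beyond the cytosolic one was -0.276, and cannot be told apart for MLN0128 and RMC-4745, whereas the bound for RMC-4627 was 0.384. More untranslated RNA in the fraction cannot be told apart either, because the upper bound for nuclear or untranslated RNAs reached 0.884 and overlaps the mitochondrial intervals. Mitochondria or their ribosomes entering the polysome fractions, or a change in mitochondrial transcripts themselves, stay open.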
